A study of Mus musculus with 2 samples.

How the data were processed

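DNase-seq was made from whole lung of newborn mice in 2 biological replicates, numbered as in the sample descriptions. The labels give the same protocol entry for both, list 2 sequencing instrument models for replicate 1 and name none for replicate 2. Peaks and hotspots were called by the authors on each library's own alignments against assembly mm10, per the notes deposited with the files. The aligner, the peak caller and their versions were not given in the sources used here. Depth was not given either, so no value was scaled by it.

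The deposited peaks were 150 bp wide, and each carried a score given by the authors, a whole number that did not exceed the peak width (2 to 150 in replicate 1 and 1 to 148 in replicate 2 on the chromosomes used). What the score measures was not given in the sources used here, and values near the width may be compressed. The score was used to describe and rank peaks within each list. It was also set against the other list, in the correlation across shared sites and in a log2 ratio of replicate 1 to 2, and the ratio can be read only relative to that of other genes, since the scale may differ between the lists. The deposited hotspots carried a −log10 q-value per the file format, at least 1.30 in both replicates and equal to 100 in 39.5% and 36.2% of hotspots. The files listed 276892 and 188726 peaks. Chromosomes 1 to 19, X and Y were used and exact duplicate intervals (26 and 23 peaks) were removed. Hotspots numbered 245628 and 170519, had median widths of 250 and 239 bp, and covered 85.6 Mb (3.23% of the genome) and 54.9 Mb (2.07%).

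GRCm38 is the assembly that mm10 denotes, and its sequence, GENCODE and RefSeq annotations were used. On all 21 chromosomes, 0 peaks or hotspots ended past the chromosome end. Peaks of both replicates were merged where they overlapped, which gave 290376 sites. Of these, 161051 held peaks of both replicates and are called shared, 107276 held only replicate 1 peaks and 22049 only replicate 2 peaks. A site was a promoter site if its centre lay within 500 bp of any annotated TSS, and otherwise exonic, intronic or intergenic in that order. A gene had an accessible promoter if any part of a shared site lay within 500 bp of an annotated TSS of that gene. Overlap of at least 1 bp counted as shared, and 100 seeded circular shifts of the other list gave the overlap by chance. Shared hotspots were merged in the same way as peaks, and their widths are those of the merged intervals.

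Each of 26 gene lists (386 genes, 385 matched to the annotation) was compared with 10000 random lists of protein-coding genes of equal size. Random lists were matched in 10 bins on promoter CpG number for promoter sites, or on gene length for distal sites more than 1000 bp from any TSS and within 50 kb of the gene. The CpG number was that within 500 bp of the 5′ end of the gene model, whichever TSS carried the site. Random lists were not matched on the number of annotated TSSs per gene. The p-values were two-sided permutation values with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. Genes are not replicates, and these p-values describe the maps of 2 libraries. Members of a Hox list lie side by side in clusters and are not independent, so that their p-values may be too small. For 24 consensus motifs, the 150 bp around each distal site were searched on both strands and compared with GC-matched windows outside hotspots by Fisher's exact test. A call needed an adjusted p under 0.05 and a ratio of at least 1.2 or at most 0.83. Neighbouring sites are not independent, so that these p-values are too small.

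The lists, the motifs, the tests and most alternatives were fixed before the data were examined. Named genes were, per list, the 3 members with the highest mean rank of their strongest promoter peak and up to 2 members, in alphabetical order, with no promoter peak. To these were added the 10 protein-coding genes with the most distal sites by nearest TSS, the 5 strongest shared sites and the 5 widest shared hotspots. Genes named outside this rule are marked as such, and some genes that the rule names are not reported here. Where 2 numbers follow a gene in parentheses, they are the scores of its strongest promoter peak in replicates 1 and 2. The alternatives covered overlap, score, promoter width, TSS choice, matching, hotspots, and each replicate alone. Together with the main setting, 9 settings were run for promoter lists, 9 for distal lists and 7 for motifs. Alternatives on gene bounds, Fgfr2, the 5′ gene end, neighbouring TSSs, nearest TSSs and CTCF windows were added after the data were seen.

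The list test was tested on simulated data over 21911 genes. It called 20 of 20 lists given extra open promoters, 0 of 20 random lists and 0 of 20 CpG-rich lists, of which 10 were called without matching. The motif test, on 20000 simulated windows, called 3 of 3 planted motifs and 1 of 21 others, the NEUROD-like E-box, whose consensus overlaps that of CTCF. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Peaks on mitochondrial DNA and unplaced scaffolds were left out of the comparisons.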

Results

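Open chromatin was mapped by DNase-seq in whole lung from newborn mice of the strain given as B6NCrl. DNase I cuts DNA preferentially where nucleosomes are displaced, so that clusters of cuts mark promoters, enhancers and insulators. The series held 1 group of 2 biological replicates, and no other tissue, age or treatment was analysed here. The comparisons were therefore between the replicates, between gene groups within the lung maps, and between accessible sites and the rest of the genome. The labels record separate biosamples under the same donor entry and give the sex as not collected. They do not state whether these are different animals or pools. For each replicate the deposited files listed narrow peaks of 150 bp and broader hotspots. Sequencing depth was not given in the sources used here.

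The promoters of Per1, a clock gene induced by glucocorticoids, and of Klf9, a transcription factor gene that glucocorticoids also induce, carried some of the strongest peaks in both replicates. Per1 had a score of 148 in replicate 1 and 139 in replicate 2, and Klf9 had 145 and 138. Peaks as strong were not limited to such genes, since the housekeeping gene Rpl13a also had 145 and 138. Promoter peaks of alveolar type 2 genes were likewise found in both replicates, as for Etv5 (145 and 132), an ETS factor gene of type 2 cells. The weaker sites differed more between the replicates. Replicate 1 listed 276480 peaks on the assembled chromosomes and replicate 2 listed 188498, a ratio of 1.47 (95% interval 1.46 to 1.48, counting error only).

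Of the replicate 2 peaks, 87.6% overlapped a replicate 1 peak by at least 1 bp (exact binomial 95% interval 87.5 to 87.8%). Of the replicate 1 peaks, 59.5% overlapped a replicate 2 peak (59.4 to 59.7%). Lists shifted along the chromosomes 100 times gave means of 3.16% and 2.16%, and the highest of these shifts were 3.31% and 2.27%. Shared peaks of replicate 1 had a median score of 66, against 36 for the peaks of replicate 1 alone. In replicate 2 the corresponding medians were 46 and 27. In the strongest decile of each list, 98.9% of replicate 1 peaks and 99.1% of replicate 2 peaks were shared. Across the 161051 sites that held peaks of both replicates, log2 scores correlated with a Spearman rho of 0.922 and a Pearson r of 0.921. These coefficients are across sites, which are not independent replicates, and the scores were the authors' own values for each peak.

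**Figure D1:**
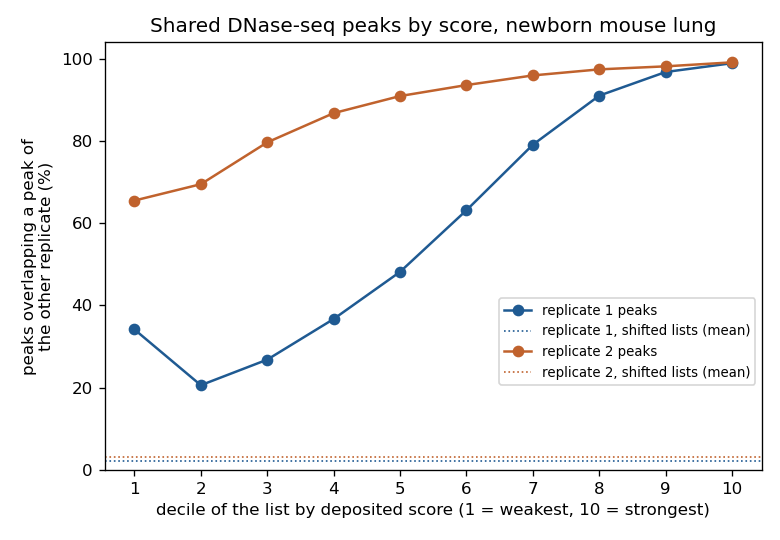
Percent of peaks overlapping a peak of the other replicate (y axis) by decile of each list ordered by deposited score (x axis), for replicate 1 (blue) and replicate 2 (orange), with the mean of 100 shifted lists as dotted lines. The share reached 98.9% and 99.1% in the strongest decile, and in replicate 1 the lowest share, 20.6%, was in the second weakest decile.

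Promoters made up 18.6% of the shared sites (29980 of 161051, exact binomial 95% interval 18.4 to 18.8%), which was 5.72 times the share of the genome within 500 bp of an annotated transcription start site (TSS). Introns held 43.2% of the shared sites, intergenic DNA 33.0% and exons 5.16%. Intergenic DNA was under-represented at 0.62 times its share of the genome. Promoter sites were also the strongest class, with median scores of 95 in replicate 1 and 71 in replicate 2, against 62 and 42 for intergenic sites. Sites of replicate 1 alone lay at promoters in 9.07% of cases (8.90 to 9.24%), and sites of replicate 2 alone in 18.4% (17.9 to 18.9%). These intervals cover counting error only.

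A shared promoter site was found for 15012 of 21911 protein-coding genes (68.5%). Promoters poor in CpG dinucleotides, the lowest 3 deciles, had such a site in 24.0% of cases, and the richest 3 deciles in 96.7%. Gene lists were therefore set against random lists of genes with similar promoter CpG numbers. Of the 26 lists fixed before the data were examined, 3 had more accessible promoters than their random lists and 6 had fewer. Any annotated TSS of a gene counted. In 62 of the 239 listed genes with a shared promoter site the strongest lay more than 500 bp from the 5′ end of the gene model, among them Vwf, Lck, Muc2, Pax5, Esam, Krt19, Cav1, Id2, Col1a1, Epor and Dazl, and 36 had no shared site at that end.

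Genes of alveolar type 2 cells, the surfactant-producing cells of the alveolus, had accessible promoters in 12 of 12 cases, against a median of 58.3% in matched random lists (central 95% of lists 41.7 to 83.3%, permutation adjusted p = 0.00312). Their strongest promoters were those of Etv5, of Cebpa (138 and 115), which encodes a C/EBP transcription factor, and of Lpcat1 (121 and 109), an enzyme of surfactant phosphatidylcholine synthesis. The Etv5 site spanned positions 22439716 to 22439865 of chromosome 16 in mm10, and the Cebpa site positions 35119076 to 35119265 of chromosome 7. The surfactant protein genes Sftpb (105 and 81) and Sftpc (94 and 65), chosen for mention after their values were seen, also had promoter peaks in both replicates.

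Fibroblast and lung mesenchyme genes had accessible promoters in 17 of 17 cases, against a median of 70.6% (47.1 to 88.2%, permutation adjusted p = 0.00347). Examples were Eln, which encodes elastin (120 and 102), Col1a1, which encodes a chain of type I collagen (118 and 96), and Tcf21, a transcription factor gene of lung mesenchyme (125 and 89). The Eln site lay at positions 134747596 to 134747745 of chromosome 5. Smooth muscle and pericyte genes had accessible promoters in 14 of 14 cases, against a median of 71.4% (50 to 92.9%, permutation adjusted p = 0.0277). Among them were Myh11, the smooth muscle myosin heavy chain gene (110 and 95), Lmod1 (104 and 81) and Kcnj8 (100 and 74). The smooth muscle call was lost with promoters of 1000 bp (permutation adjusted p = 0.0875), with only peaks above the median score (0.375) and with replicate 1 alone (0.0890). Over all its alternatives the adjusted p of this list ran from 0.0026 to 0.375.

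Posterior Hox genes, groups 9 to 13, had fewer accessible promoters than matched genes. A shared site was found in 6 of 16, against a median of 93.8% in matched random lists (81.2 to 100%, permutation adjusted p = 0.0013, from the smallest p the permutations can give). Hoxa9 and Hoxa11 had no promoter peak in either replicate, whereas Hoxa10 had peaks with scores of 101 and 85. In replicate 1 alone, 9 of 16 posterior Hox genes had a promoter peak, still below the random lists (permutation adjusted p = 0.00173). Anterior Hox genes, groups 1 to 5, had accessible promoters in 14 of 15 cases against a median of 86.7%, which did not pass the test (permutation adjusted p = 0.639). Among the strongest were Hoxa5, a gene needed for lung development (130 and 109), and Hoxb5 (126 and 96). With only the 5′ end of each gene model as TSS, the anterior list was called below its random lists, with 53.3% of members accessible (permutation adjusted p = 0.0432). The accessible members without a shared site at that end were Hoxb1, Hoxb2, Hoxb3, Hoxc4, Hoxc5 and Hoxd3. Their strongest shared sites lay at other annotated TSSs, 1004 to 46213 bp from that end.

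Genes of several other tissues had few accessible promoters in newborn lung. None of the 12 pancreas genes had a shared promoter site, Cel and Cpa1 among them, against a median of 50% (25 to 75%, permutation adjusted p = 0.0013). Of 12 germ cell genes only Dazl had a shared site (127 and 100), against a median of 66.7% (permutation adjusted p = 0.0013). Of 19 liver genes only Alb, which encodes albumin, had a shared site, with weak scores of 36 and 40 (permutation adjusted p = 0.0013), and Afp and Ahsg had none. Of 12 intestine genes, Alpi and Apoa4 were without a peak and only Muc2 had a shared site (permutation adjusted p = 0.013). Skeletal muscle genes had accessible promoters in 4 of 18 cases, against a median of 61.1% (permutation adjusted p = 0.00594). These were Mylpf (144 and 140), Ryr1 (90 and 78), Pygm (90 and 63) and Actn3 (59 and 24). Muc2 and Actn3 were named after their values were seen, and the Mylpf site lies within 1000 bp of a TSS of another gene. With promoters of 1000 bp the calls for liver (permutation adjusted p = 0.224), intestine (0.55) and skeletal muscle (0.445) were lost, and intestine also lost its call with hotspots (0.238). With replicate 1 alone, 3 of 12 germ cell genes (permutation adjusted p = 0.0039), 6 of 18 skeletal muscle genes (0.0178) and 2 of 12 intestine genes (0.092, no call) had a promoter peak, and with replicate 2 alone 1 of 12 pancreas genes (0.00594) did. The genes with such a peak but no shared site were Ddx4 and Pou5f1 in the germ cell list, Acta1 and Tnni2 in that of skeletal muscle, Vil1 and Lgals4 in that of intestine, where the replicate 1 peak of the shared Muc2 site lay outside the 500 bp limit, and Cela3b in that of pancreas, named after their values were seen.

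The other 16 lists, apart from the anterior Hox genes, did not pass the test. Lung epithelial transcription factor genes had accessible promoters in 14 of 14 cases (permutation adjusted p = 0.244), with the strongest peaks at Id2 (144 and 122), Irx2 (139 and 123) and Klf5 (137 and 120). Alveolar type 1 genes, of the thin gas-exchange cells, were accessible in 12 of 13 cases (0.673), led by Gprc5a (137 and 115), Cav1 (125 and 103) and Emp2 (125 and 98). Endothelial genes were accessible in 19 of 22 cases (0.244), among them Vwf (115 and 97, at an annotated TSS 56542 bp inside the gene), Esam (113 and 98) and the VEGF receptor gene Kdr (95 and 76). Airway epithelial genes were accessible in 8 of 15 cases (0.639), with Tppp3 (138 and 123) and the ciliated cell regulator Foxj1 (121 and 102) open and Dnah5 and Krt15 without a peak. Mesothelial genes were accessible in 5 of 8 cases, with Krt19 the strongest (122 and 107).

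Blood cell promoters were open in part. Myeloid genes had accessible promoters in 10 of 18 cases, led by Irf8 (129 and 108) and Cd68 (114 and 93), while C1qb and Cx3cr1 had none. Lymphoid genes were accessible in 6 of 14 cases, among them Lck (110 and 94, 16956 bp inside the gene) and Pax5 (96 and 84, 5842 bp inside), while Cd79a had none. Erythroid genes were accessible in 7 of 15 cases, among them the transferrin receptor gene Tfrc (122 and 110) and Epor (85 and 71), while Gata1 had none. The alpha-globin gene Hba-a1 also had no promoter peak, but it has a near-identical copy in which reads may not have been placed. Cardiac muscle genes were accessible in 8 of 17 cases, neuronal genes in 12 of 19, kidney genes in 7 of 12 and epidermal genes in 3 of 12. With replicate 1 alone epidermal genes had a promoter peak in 5 of 12 cases and cardiac muscle genes in 12 of 17, and with replicate 2 alone lymphoid genes in 9 of 14, with no call. Morphogen signalling genes were accessible in 14 of 15 cases, with Axin2 the strongest (140 and 124). All 10 glucocorticoid response genes, all 14 cell cycle genes and all 20 housekeeping genes had accessible promoters, against medians of 80%, 92.9% and 90% in their CpG-matched random lists, and did not pass the test. Without matching on CpG number, lung epithelial transcription factor and cell cycle genes (permutation adjusted p = 0.0232 for each) and housekeeping genes (0.00433) were called above and epidermal genes (0.0221) below. With only peaks above the median score, neuronal genes were called below (permutation adjusted p = 0.00104).

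**Figure D2:**
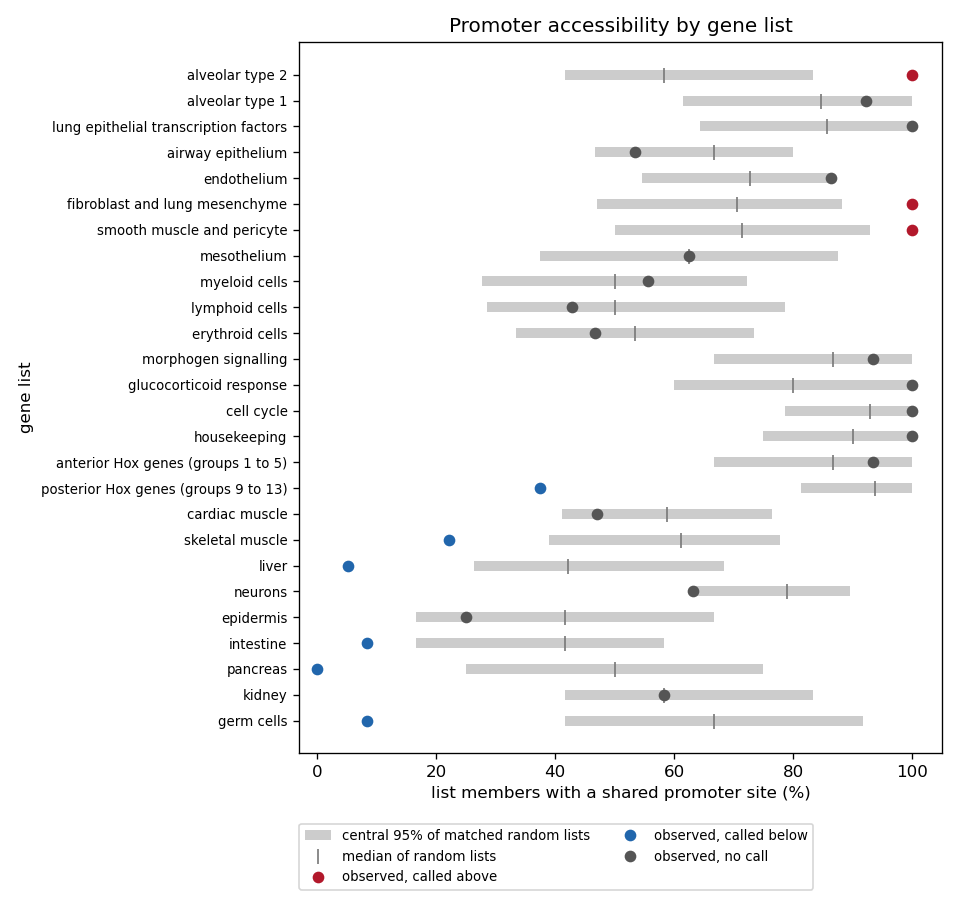
Percent of the members of each gene list with a shared promoter site (points, x axis) against the central 95% and the median of 10000 random lists matched on promoter CpG number (grey bars and ticks). Red points were called above (3 lists), blue points below (6 lists) and grey points neither, at an adjusted p under 0.05.

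Distal sites, more than 1000 bp from any TSS, made up 120868 of the shared sites (75.05%). Alveolar type 1 genes had a mean of 16.3 shared distal sites within 50 kb, against a median of 8.85 for random lists matched on gene length (5.85 to 12.2, permutation adjusted p = 0.0052). Emp2 had 22 such sites, Cav1 had 16 and Gprc5a had 15. With replicate 1 alone the mean was 27.4 against 15.5. The call was lost without matching on gene length (permutation adjusted p = 0.0832) and when a site was counted only for the gene of its nearest TSS, at any distance (0.0711).

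Morphogen signalling genes had a mean of 33.1 distal sites, against 11.3 (7.73 to 15.7, permutation adjusted p = 0.0312), a value that rested largely on Fgfr2. Fgfr2 encodes a fibroblast growth factor receptor needed for lung branching. Its GENCODE bounds run over 2961 kb and took in 259 distal sites, while its RefSeq bounds of 104 kb took in 24. Without Fgfr2 the list had a mean of 17.0 (permutation adjusted p = 0.0572), and with RefSeq bounds for all genes 18.1 (0.0338). With replicate 1 alone it had 57.4 against 19.8. Glucocorticoid response genes had a mean of 23.5 distal sites against 12.8 and endothelial genes 14.5 against 10.4, and neither passed the correction (permutation adjusted p = 0.0849 and 0.217). The glucocorticoid list was called above without matching (permutation adjusted p = 0.0295) and with only peaks above the median score (17.2 against 6.5, 0.0416). Alveolar type 2 genes had 11.7 against 8.38, with no call, and were called above with only peaks above the median score (8.75 against 4.67, permutation adjusted p = 0.0416). Lung epithelial transcription factor genes had 10.9 against 8 and fibroblast genes 13.2 against 10.4, with no call. In a setting added after the data were seen, sites were counted only for the gene of their nearest TSS, at any distance and without the 50 kb limit. Both lists were then called above, with 27.7 against 4 (permutation adjusted p = 0.0026) and 15.3 against 6.29 (0.00867). By that count Id2 had 68 sites, against 14 within 50 kb, and Klf5 had 30 against 7. With replicate 1 alone the mean over all protein-coding genes was 16.4, against 9.34 for shared sites. There the glucocorticoid list had 46.8 against 22.6 (permutation adjusted p = 0.052), endothelial genes 23.4 against 18.3, alveolar type 2 genes 18.6 against 14.6, lung epithelial transcription factor genes 21 against 14 and fibroblast genes 23.4 against 18.1, with no call. By the permutation test, 0 of 26 lists had fewer distal sites than their random lists, and 0 did so at an unadjusted p under 0.05.

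**Figure D3:**
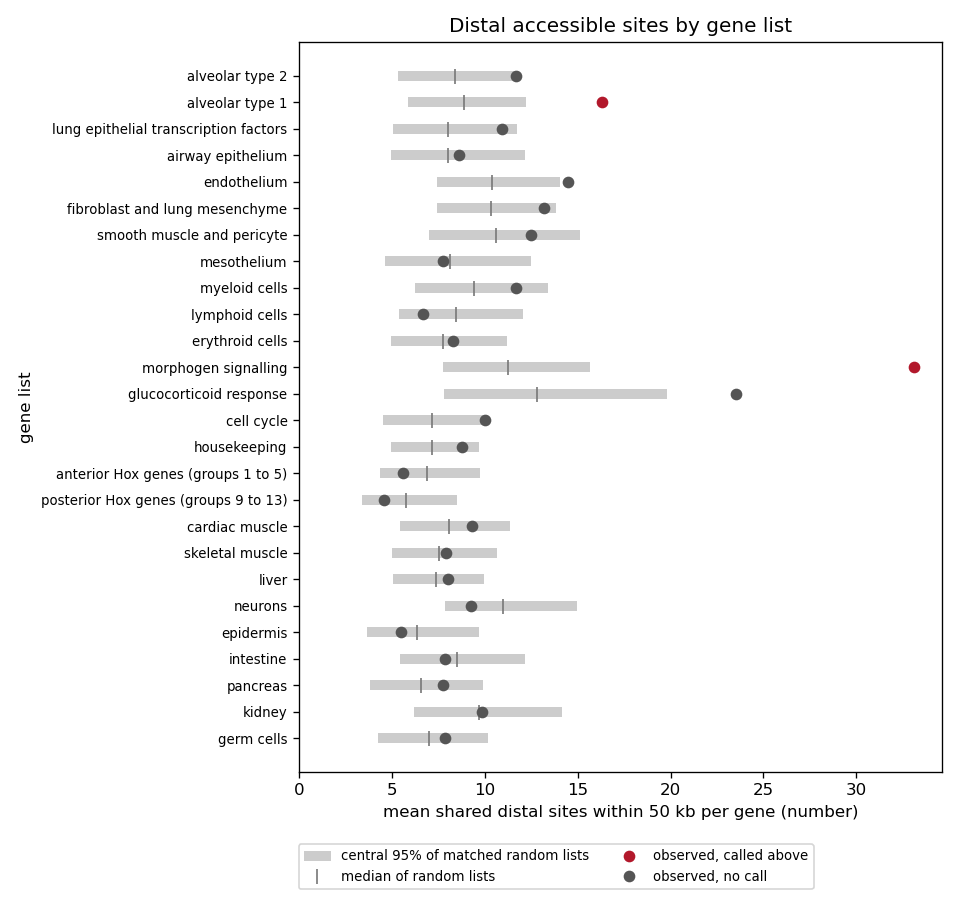
Mean number of shared distal sites within 50 kb of the genes of each list (points, x axis) against the central 95% and the median of 10000 random lists matched on gene length (grey bars and ticks). Alveolar type 1 genes (16.3) and morphogen signalling genes (33.1) were called above, the latter not without Fgfr2 (17.0, no call).

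By nearest TSS at any distance, the protein-coding genes with the most shared distal sites were Adgrl2 (117), Zfp608 (113), Pde4d (107), Zmiz1 (102), Rbms3 (100), Zfhx3 (98), Auts2 (93), Foxp1 (92), Lpp (92) and Sox5 (91). Many of these sites may lie far from the gene, since Adgrl2 had only 18 within 50 kb. Foxp1 encodes a forkhead factor of lung epithelium, and Pde4d a phosphodiesterase that degrades cyclic AMP. The strongest shared site lay at the promoter of Hjurp, 13 bp from its TSS, at positions 88277536 to 88277705 of chromosome 1, with scores of 150 and 148. The next 4 lay near the TSSs of Dnpep (150 and 141), Rnf31 (147 and 143) and Ube2s (148 and 141), and 18490 bp from the nearest TSS, that of Fos, at positions 85455316 to 85455485 of chromosome 12 (146 and 143). The widest shared hotspot spanned 9294 bp near Tnrc18, and the other 4 lay over Id2 (7483 bp), Neat1 (7061 bp), Marcks (6481 bp) and Bcl6 (6440 bp). These widths are of intervals merged over both replicates. The widest unmerged hotspot was 9290 bp in replicate 1 and 6249 bp in replicate 2.

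Distal sites were rich in the consensus sequence of CTCF, the main insulator protein of vertebrates. It occurred in 6.28% of 120867 distal sites and in 0.196% of GC-matched windows, a ratio of 32.02 (95% interval 28.1 to 36.4). With all distal peaks of replicate 1 alone the CTCF ratio was 19.9, with those of replicate 2 alone 30.2, and in the middle 50 bp of the shared sites 65.4. The NFI consensus, bound by nuclear factor I proteins, had a ratio of 11.7 (9.43 to 14.5) and that of C/EBP 5.11 (4.73 to 5.52). AP-1 had 3.39 (3.25 to 3.53), the glucocorticoid receptor 3.13 (2.73 to 3.58), TEAD 2.59 (2.47 to 2.71) and FOXA 2.23 (2.15 to 2.32). The consensus of NKX2-1, a regulator of lung epithelial identity, occurred in 9.37% of sites and 5.40% of windows, a ratio of 1.74 (1.69 to 1.79). Against windows 1000 bp to the side of the sites, each of the motifs above was still called enriched, with a lower ratio. CTCF had 24.8 there, NFI 10.97, C/EBP 3.52, AP-1 3.04 and the glucocorticoid receptor 2.68. TEAD had 2.48, NKX2-1 1.57 and FOXA 1.497. Mean GC was 44.8% in those windows and 48.4% in the sites.

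Of the 24 motifs, 18 were enriched by Fisher's exact test with a ratio of at least 1.2, and their largest adjusted p was 2.04e-09. The others among them were RFX (8.50), MEF2 (5.64), HNF1 (13.7), KLF/SP (1.97), ERG-like ETS (1.91), a TCF21-like E-box (1.86), grainyhead (1.71), ETS with CpG (1.63), GATA (1.40) and RUNX (1.22). The ratios of KLF/SP (2.26), ETS with CpG (2.37) and the TCF21-like E-box (2.11) were higher against windows 1000 bp to the side. Control windows were matched on GC and not on CpG dinucleotides, which the KLF/SP and ETS with CpG consensus sequences require. Their ratios therefore cannot be told apart from CpG content. The HNF1 ratio came from only 41 sites and 3 windows (4.23 to 44.1), and was 3.71 with replicate 1 alone, 5.67 with replicate 2 alone and 2.28 against windows 1000 bp to the side. SOX (1.02), TBX (0.951), POU (1.07), HNF4 (1.19), the SRF CArG box (1.19) and a NEUROD-like E-box (1.16) were not called. By Fisher's exact test 0 motifs were depleted, and 0 had a ratio below 1 at an unadjusted p under 0.05. A consensus match does not show that the protein was bound, and related proteins share a consensus. RUNX was not called against the side windows (ratio 1.04), with only peaks above the median score (1.17) or with replicate 1 alone (1.18), the MEF2 ratio was 2.44 against the side windows, and that of RFX was 5.67 against them and 12.8 with replicate 2 alone. The NEUROD-like E-box and the SRF CArG box were called enriched against the side windows (1.25 and 1.21) and with only peaks above the median score (1.21 and 1.24), the former also in the middle 50 bp (1.32). Without windows holding a CTCF consensus, a setting added after the data were seen, the ratio of the NEUROD-like E-box was 1.05, with no call.

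**Figure D4:**
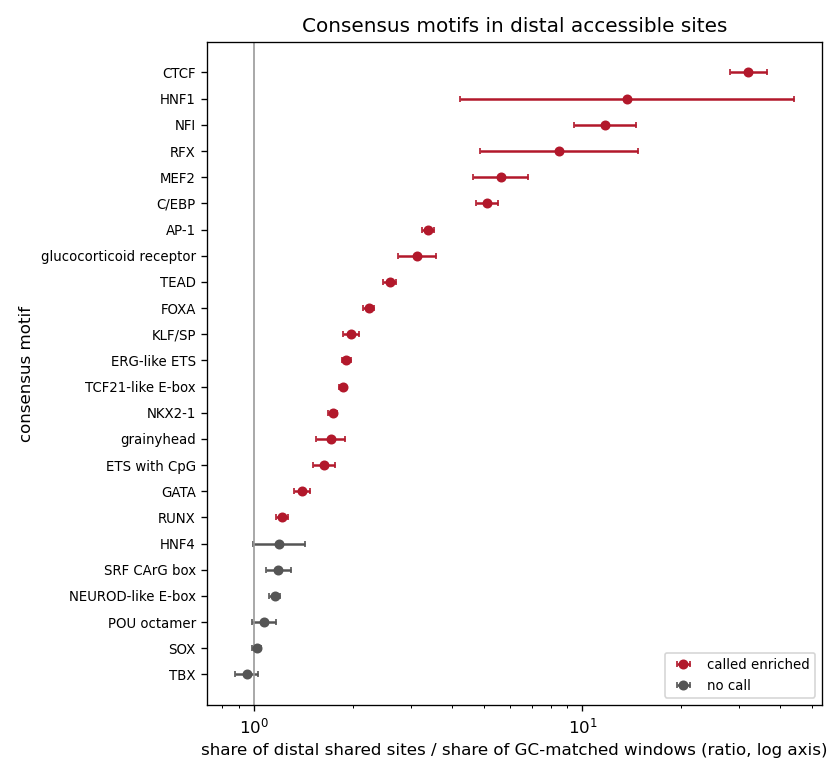
Ratio of the share of distal shared sites with each consensus motif to the share of GC-matched windows (points, x axis, logarithmic) with 95% intervals, for 24 motifs. CTCF (32.02) lies farthest to the right, and 18 motifs (red) were called enriched.

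The X chromosome carried 40.2 peaks per Mb in replicate 1 and 28.2 in replicate 2, which was 0.357 and 0.368 times the autosomal density. Autosomes ranged from 88.2 to 159 peaks per Mb in replicate 1 and from 60.5 to 108 in replicate 2, so that X lay below every autosome in both replicates. Chromosome 11 was the densest autosome in both. Chromosome Y carried 84 and 70 peaks, 0.00846 and 0.0104 times the autosomal density, or 26 peaks and 0.00382 times in replicate 1 with its weaker peaks left out to the number in replicate 2. The Y genes Kdm5d (67 and 70), Eif2s3y (77 and 81), Uty (93 and 87) and Ddx3y (89 and 76) had promoter peaks in both replicates. These genes were chosen outside the rule for named genes.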

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

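Among the tests in this part, both tests of random calls near the threshold were chosen after their results were seen.

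Signal appeared in sequences left out of the comparisons. Mitochondrial DNA held 26 peaks in replicate 1 and 24 in replicate 2, with a median score of 150 in both. Unplaced scaffolds held 360 and 181 peaks, with median scores of 36 and 37.

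Replicate 1 listed more peaks than replicate 2. Background calls are argued against as the source of all the extra distal sites. The CTCF consensus was 4.68 times as frequent in distal sites of replicate 1 alone as in GC-matched windows (95% interval 3.95 to 5.54). It lay in 0.84% of these sites, against 6.28% of shared distal sites and 0.18% of the windows. A mean ratio cannot give the share of the sites that is background, which stays open. A different cell mix may contribute, since 3 of 26 lists differed in their mean log2 score ratio of replicate 1 to 2 at distal sites: endothelium (0.53) and fibroblast and lung mesenchyme (0.59) lay above matched lists, and posterior Hox genes (0.34) below. All 26 lists had a mean ratio above 0, the score scale is not given, and a shift common to all lists is not what a cell mix alone would give. Higher sensitivity with the same cell mix stays open, because 2 lists, lung epithelial transcription factors and anterior Hox genes, differed in the share of replicate 1 distal peaks without a partner, between the bounds of 0 and 3 set for that test. Members of each Hox list lie side by side in clusters and share distal sites, while random lists hold scattered genes. The p-values of the Hox lists in these tests may therefore be too small.

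Sites of replicate 2 alone lay at promoters about as often as shared sites. Random calls near the threshold are argued against as the source of all distal sites of replicate 2 alone. The CTCF consensus was 5.82 times as frequent there as in GC-matched windows (95% interval 4.05 to 8.37). It lay in 1.25% of these sites, against 6.28% of shared distal sites and 0.215% of the windows, so the share of random calls stays open. Random calls also stay open for the promoter sites, since the promoter share, 5.65 times that of the genome, is the pattern itself and excludes nothing. A possible explanation is second peaks in or beside regions that replicate 1 also has open, since 74.1% of these promoter sites overlapped a replicate 1 hotspot by at least 1 bp. The same held for 29.0% of the sites elsewhere. How often random calls at promoters would overlap a replicate 1 hotspot was not computed. The 74.1% therefore does not separate second peaks from random calls there. Of the promoter sites of replicate 1 alone, 22.4% overlapped a replicate 2 hotspot, but hotspots covered 54.9 Mb in replicate 2 and 85.6 Mb in replicate 1. Such an overlap does not show that the whole site lay inside the hotspot. No biological explanation was tested, since the design has 1 group.

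Chromosome Y carried few peaks. A lack of male tissue is argued against by promoter peaks in both replicates at 4 of 4 genes tested, Kdm5d, Eif2s3y, Uty and Ddx3y. Whether repeated sequence, in which reads could fail to be placed, explains all of this stays open: 4.83% of Y positions were unique on their chromosome, against 73.1% of X positions. Per Mb of sequence, Y held 0.953 peaks in replicate 1 and 0.794 in replicate 2, and X held 40.2 and 28.2. Per Mb of unique positions, Y held 12.2 and 9.41 and X held 53.5 and 37.5, so the gap was narrower there. Unique positions held the centres of 52 of 84 and 40 of 70 Y peaks, and of 6396 of 6571 and 4480 of 4614 X peaks. Some Y peaks were thus called in sequence repeated on the chromosome. The density of peaks at unique positions, Y over X, was 0.251 in replicate 2 and 0.228 in replicate 1, around the lower bound set for that test. The share of male tissue in each library, with sex not collected, also stays open.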

How the results depend on the processing

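The 5′ gene end, nearest TSS, RefSeq bounds, Fgfr2, neighbouring TSS and CTCF window settings were chosen after seeing the data. No paired analysis was possible because there was 1 group. The shared percent of replicate 1 and 2 peaks was 55.8 and 82.1 with an overlap of 50% and also with centres within 75 bp, which is the same rule for peaks of equal width. It was 74.5 and 75.1 with lists of equal length, 64.7 and 95.002 for peaks above the median score, and 59.3 and 91.4 for hotspots. The Spearman correlation of scores was 0.919 without the strongest 1%. The promoter share was 26.8% above the median score, 24.95% within 1000 bp, 16.2% with protein-coding TSSs, and 14.7 to 18.5% with each replicate alone. Without matching, 6 promoter lists lay above, and within 1000 bp 3 lay below. Anterior Hox genes turned from above (no call) to below with the 5′ gene end, at 53.3%. Distal lists called above numbered 4 above the median score and 1 without Fgfr2, and 1 list lay below without matching. With replicate 1 reduced to the number of replicate 2 by leaving out its weaker peaks, the X and Y ratios were 0.264 and 0.00382. Replicate 2 had 0.368 and 0.0104 with the same number of peaks, and the cause of this difference was not tested. TBX was called depleted in the middle 50 bp, so 1 motif was. Over all alternatives, comparisons of a single list or motif kept their side of the threshold in 194 cases for promoter lists (8 calls lost, 5 gained), 199 for distal lists (3 lost, 6 gained) and 133 for motifs (3 lost, 6 gained). For promoter lists 1 further case, the anterior Hox genes with the 5′ gene end, gained a call in the reversed direction. Other causes were not tested. No ratio could be formed for HNF1 in the middle 50 bp or for CTCF without its own windows. Taking peaks above the median leaves the peak number ratio nearly fixed by construction. Unknown depth limits what a missing peak shows.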

Other observations

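The test of promoter strength in this part, and its list of immediate early genes, were chosen after the data were seen.

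Among genes with an accessible promoter, glucocorticoid response genes had stronger peaks than genes with similar CpG numbers at the 5′ end. Their strongest promoter peaks lay on average at percentile 98.3 of all peaks (mean over both replicates), against a median of 85.6 for matched random lists (permutation adjusted p = 0.0014, 10 genes). Housekeeping genes reached 98.0 against 89.0 (permutation adjusted p = 0.0014, 20 genes). Any annotated TSS counted. The strongest shared sites of Nr3c1, Sgk1, Dusp1, Tsc22d3, Fkbp5 and Errfi1 lay 997 to 112352 bp from the 5′ end of the gene model. Nr3c1, Sgk1 and Dusp1 had no shared site at that end. For these genes the matching did not cover the sequence at the peak, and the 5′ end alone was not tested. For every list in this test of strength, the number of annotated TSSs was not matched either. Genes with more TSSs had more chances of a strong peak. Those other than Nr3c1 were named after their values were seen. A list of 12 immediate early genes, which cells switch on within minutes of a stimulus, was drawn up after a site near Fos had been seen among the 5 strongest. Its mean percentile of 98.4, against 90.1, describes these genes and tests nothing.

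Promoters of neuronal genes that were accessible were on average weaker than those of matched lists, at percentile 57.6 against 88.3 (permutation adjusted p = 0.0014, 12 genes). Not all were weak, since the strongest, Syn1 (110 and 82), Camk2a (104 and 70) and Eno2 (77 and 60), lay at mean percentiles 91.1, 86.5 and 74.9. Accessible anterior Hox promoters lay at 72.1 against 86.9 (permutation adjusted p = 0.0301, 14 genes), and accessible posterior Hox promoters at 68.4 against 92.8 (permutation adjusted p = 0.0193, 6 genes). The strongest shared sites of Hoxa3, Hoxb1, Hoxb2, Hoxb3, Hoxc4, Hoxc5 and Hoxd3 lay 1004 to 46213 bp from the 5′ end of the gene model. Of these only Hoxa3 had a shared site at that end, and all were named after their positions were seen. Hoxa5 (130 and 109) stood above most Hox promoters, and Hoxd1 (39 and 34) and Hoxc4 (42 and 31) were among the weakest, and the last pair were named after their values were seen. The adjustment was over 21 lists, and alveolar type 2 (89.1 against 79.8) and lung epithelial transcription factor promoters (93.5 against 87.4) did not pass.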
